A study of Mus musculus with 48 samples.

How the data were processed

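Exon inclusion was measured by multiplex amplicon sequencing of spliced transcripts (SPAR-seq) in N2A cells, a mouse neuroblastoma line, in 48 libraries from 24 groups of 2. Per the labels, 22 groups received siRNA pools at 25 nM against named proteins, 1 group received a non-targeting siRNA and 1 was untreated, and RNA was taken 48 hours after transfection. Regions of 108 genes were amplified in a first PCR of 30 cycles with a mixture of 50 primer pairs, and barcodes were added in a second PCR of 15 cycles. The annotated plate was the replicate number in all 48 libraries, and the treatment code of each library was that of its label.

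The submitters' processing notes name Bowtie (version not given) and the genome builds NCBIM37 and mm9. In the table deposited by the authors each cell is text that gives the inclusion and the exclusion reads of an event in a library. How the authors turned junction reads into these values is not stated. Inclusion plus exclusion was a whole number (within 0.011) in all 8293 filled cells, but 41.3% of the inclusion values were not whole. A table for 33 events holds the percent of inclusion (PSI) of each replicate as computed by the authors, and a score, the strictly standardised mean difference against the negative controls, also computed by the authors. Of 1584 PSI values deposited by the authors, 1531 equalled the PSI computed here from the reads within 0.06 points, and the others belonged to 2 events of Rnf114. The junction table gives no coordinates or exon lengths. Gene symbols were looked up in a RefSeq gene table of assembly GRCm38.p6: 102 of 108 were current symbols, 5 were older symbols and 1 was not found. No coordinates were taken from it.

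PSI was 100 times the inclusion reads over the inclusion plus exclusion reads. An event was kept if it had 20 or more reads in at least 36 of the 48 libraries and a mean PSI from 1 to 99. Of 174 events in the table, 4 were amplicons with no alternative event, 52 were left out for reads and 32 for their mean PSI, which left 86 events in 70 genes. A comparison tested the kept events with 20 or more reads in each of its libraries. In the event names a capital E was taken to mark an exon with a label in the junction table, called a target event here, and 69 of the 86 events were targets. A small e was taken to mark a further exon or splice site of the same amplicon, which shares reads with the target and is not independent of it. Both readings were inferred from the tables and are unsure.

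The log2 of inclusion plus 0.5 over exclusion plus 0.5 was fitted with 24 group means over all 48 libraries, and the variance of each event was moderated over events with squeezeVar of limma 3.58.1 in R 4.3.3, the moderated test of limma. Differences are log2 odds ratios. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an event was called at an adjusted p under 0.05. The test planned before the data were examined was the quasi-likelihood test of edgeR, which was not used because the inclusion values are not whole counts. The limma test had been planned as an alternative and took its place. The limits on mean PSI, and a quasi-binomial test of the reads with the dispersion moderated by squeezeVar, were added after the data were seen.

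On simulated data for the Srrm4 comparison (20 draws of 86 events with the fitted spread), the test called 37.5% of events with a log2 odds ratio of 1, 78.3% with 2 and 90% with 3. It called 0.995% of unchanged events, and 3.57% of calls were false. On 66 events without missing values its p-values differed from those of limma's eBayes by at most 1.4e-16.

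The reads of an amplicon were taken as the highest inclusion plus exclusion reads among the events of its gene. A library total was the sum of these values over genes, not a count of sequenced reads. Library totals ran from 28023 reads (Rbm17 replicate 1) to 75823 (Ippk replicate 2), with a median of 50738.5. The median number of reads behind a PSI value was 150. The 95% Wilson interval of a PSI of 50 spans 7.9 points each way at 150 reads and 20.1 points at 20 reads. Reads of a PCR without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

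Each siRNA group was compared with the non-targeting group, and the untreated group with it as a control. Further comparisons were the double Srrm4 and Srrm3 knockdown against each single knockdown, the interaction of the 2 knockdowns on the log odds scale, Ep300 against CBP, and the overlap of Rnps1 and Srrm4. Because both sides of that overlap share control libraries, it was compared with the product of the 2 counts over the events tested and with the untreated libraries as the control of 1 side, and the covariance of log2 odds ratios with that in 1000 simulated pairs of unchanged groups.

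Events were named by a rule fixed before the data were examined. For Srrm4, Srrm3, the double knockdown and Rnps1 it took, among called events with both knockdown libraries beyond both control libraries, up to 12 with the largest fall and up to 12 with the largest rise in PSI. For other comparisons it took up to 3 each way. Events of Mef2d, Eif4g3 and Vav2, the genes of a fixed list of 12 with events on the panel, were added whether called or not. Outside this rule, Ptbp2.E1 in Fam133b, Ippk and Srrm4 libraries, Sbf2.E2 in Srrm4 libraries, the 4 events of the interaction (Ubr4.E1, Zdhhc20.E1, Mef2d.E1 and Acap2.E1), Ubr4.E1 and Kifap3.E1 in untreated libraries, the events named as shared by Rnps1 and Srrm4, Gse1.e1 in untreated libraries, the 2 events with the smallest p of the Fxr1 and Fbxw11 comparisons, the values of Mef2d.E1, Kif1b.E1 and Clasp2.E1 in untreated libraries, the events whose calls were tallied over knockdowns, and events named in gene lists were named after their values were seen.

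Gene lists fixed beforehand covered vesicle traffic and endocytosis, transcription and chromatin, RNA processing and translation, synapse, adhesion and ion channels, and protein kinases, phosphatases and signalling scaffolds. Lists were counted on target events. Results of some planned lists and events were left out of the text and of the heatmap, and the counts of called events include those events.

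The share of the library total, as defined above, taken by each of 77 amplicons was tested with limma on the log2 scale in the same design. It served as a check that the Srrm4 and Srrm3 amplicons fell with their siRNA. Shares after an endpoint multiplex PCR are not calibrated expression levels.

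Alternatives tried were the untreated group or the mean of both control groups as the control, the mean of the other groups with the same i5 barcodes as the reference, a minimum of 100 reads or 1 read, a replicate block, a fit on only the groups compared, a required PSI difference of 10 points, leaving out each library, and those added after the data were seen: the quasi-binomial test, no limit on mean PSI, a prior variance trended on reads, target events alone, and, for amplicon shares, median-of-ratios scaling, the untreated control, the replicate block and leaving out each library. Calls per event were also counted under the other references, after the data were seen. The reference of groups with the same i5 barcodes consists mostly of other knockdowns and moves with events that respond in them. When a library is left out, the lone library of its group is assumed to vary like the other groups. A comparison of microexons with longer exons was planned and not made, since exon lengths were not among the values used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.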

Results

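Exon inclusion was measured in 48 libraries of N2A mouse neuroblastoma cells, in 24 groups of 2 libraries each. In 22 groups siRNA had been directed against splicing factors, other RNA-binding proteins, chromatin proteins or proteins of other kinds, and 1 of these groups received siRNA against both Srrm4 and Srrm3. The control groups were transfected with a non-targeting siRNA or left untreated. Inclusion is given as percent spliced in (PSI), the share of an amplicon's reads that include the exon, for 86 alternative events in 70 genes. Library totals, summed over amplicons, ran from 28023 to 75823 reads, with a median of 50738.5. The Mef2d amplicon took 23.9% of the summed reads. Across events, which are not independent replicates, the PSI of paired replicates had a Pearson r of 0.967 to 0.992. The labels do not say whether replicates were separate cultures, so the p-values below measure only the spread between these samples. The spread of each event was pooled over all 24 groups, although replicate scatter differed between groups. The median absolute PSI difference of replicates was 1.73 points with Srrm4 and 4.06 points with Fxr1 siRNA. A p-value therefore does not follow the scatter of the groups compared. All values with ± are means with their SD over n = 2 libraries. The untreated, Srrm4, Srrm3, Rbfox2, Elavl2, hnRNP K, Gpatch8, Rnps1, Cdc5l, Strbp, Fxr1 and Ep300 groups carried i5 barcode set 1 in replicate 1 and set 3 in replicate 2, and the non-targeting, double-knockdown and other groups carried sets 2 and 4. Each pair of sets is called a row here, and comparisons across the rows are confounded with the row.

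No event was called between the control groups. Mef2d.E1, in the gene of a transcription factor of neurons and muscle, had a PSI of 87.9% ± 3.0 (SD, n = 2) in untreated and 88.2% ± 1.9 (SD, n = 2) in non-targeting libraries. Kif1b.E1, in the gene of a kinesin that moves cargo along axons, stood at 92.1% ± 2.4 and 92.5% ± 1.9. Clasp2.E1, in the gene of a protein at growing microtubule ends, stood at 66.9% ± 2.8 and 61.6% ± 0.1. The limma test called 0 of 81 events, with 2 events (Kifap3.E1 and Ubr4.E1) at an unadjusted p under 0.05, and the quasi-binomial test called 0. Without untreated replicate 1 the count was 1. The largest difference was that of Gse1.e1, at 52.5% ± 27.2 in untreated and 73.6% ± 4.7 in non-targeting libraries (adjusted p = 0.904). An absent call does not show equal inclusion, since on simulated data the test called 37.5% of events with a log2 odds ratio of 1.

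Srrm4 siRNA lowered inclusion of exons in Kif1b, Clasp2 and Mef2d, among others, and raised that of an exon in Sgce. Srrm4, also called nSR100, is a neuronal SR-related protein that activates inclusion of neural exons, and the title of the series concerns how neuronal microexons linked to autism are recognised. Kif1b.E1 fell from 92.5% ± 1.9 to 16.1% ± 0.2 (log2 odds ratio -6.02, SE 0.33, adjusted p = 3.9e-15). Clasp2.E1 fell from 61.6% ± 0.1 to 1.8% ± 0.0 (log2 odds ratio -6.46, SE 0.23, adjusted p = 1.9e-19), and Mef2d.E1 from 88.2% ± 1.9 to 55.3% ± 0.4 (log2 odds ratio -2.60, SE 0.23, adjusted p = 1.7e-10). Sgce.E1, in the gene of epsilon-sarcoglycan, rose from 52.6% ± 0.6 to 75.4% ± 5.2 (log2 odds ratio 1.48, SE 0.19, adjusted p = 2.2e-07).

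The test called 28 of 77 events with Srrm4 siRNA, 21 lower and 7 higher, and 25 of them differed by 10 points or more. Dock4.E1 fell from 56.3% ± 7.2 to 9.5% ± 0.5, and Herc4.E1, in a ubiquitin ligase gene, from 85.4% ± 7.0 to 41.6% ± 3.8. Acbd5.E1, in the gene of a peroxisomal acyl-CoA binding protein, fell from 44.5% ± 1.2 to 6.4% ± 0.5. Senp6.E1, in a SUMO protease gene, fell from 97.5% ± 0.7 to 63.3% ± 0.5 (adjusted p = 9.1e-11). Asph.E1, in the gene of an aspartyl hydroxylase, fell from 40.8% ± 2.2 to 8.6% ± 2.3. Acap2.E1, in the gene of a GTPase-activating protein for Arf6, fell from 99.1% ± 0.1 to 67.1% ± 0.4, and Mon2.E1, in a gene of endosome-to-Golgi traffic, from 98.9% ± 0.4 to 70.2% ± 2.2. Ppp3cb.E1, in the gene of a calcineurin catalytic subunit, fell from 96.1% ± 0.2 to 72.8% ± 0.5. Mapk8.E1, in the gene of the kinase JNK1, fell from 49.8% ± 0.0 to 20.1% ± 0.3 while Mapk8.e2 of the same amplicon rose from 50.9% ± 0.7 to 80.4% ± 0.6.

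Inclusion also rose with Srrm4 siRNA in Numa1.E1, in the gene of a spindle pole protein, from 69.8% ± 9.0 to 92.0% ± 0.3, and in Dlg1.E2, in a synaptic scaffold gene, from 0.3% ± 0.1 to 3.1% ± 0.7 (adjusted p = 3.2e-06). Dennd5a.E1, in the gene of a Rab activator, rose from 72.2% ± 9.6 to 88.6% ± 0.5, Phf21a.E2, in the gene of a subunit of a histone demethylase complex, from 0.8% ± 0.3 to 11.6% ± 0.9, and Cit.E1, in the gene of citron kinase, from 3.0% ± 0.5 to 12.3% ± 5.2. These 3 calls did not hold in every setting. The Dennd5a call was lost without Srrm4 replicate 1 (log2 odds ratio 1.40), Srrm4 replicate 2 (1.52) or non-targeting replicate 1 (0.97), with untreated as the control (0.77) and in a fit on only the groups compared (1.46). The Phf21a call was lost without Srrm4 replicate 1 (3.39) or non-targeting replicate 1 (3.28). The Cit call was lost without the same libraries (1.56 and 1.91) and with untreated as the control (1.16).

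Of the listed genes, Eif4g3, a translation initiation factor gene, had a target event, Eif4g3.E2, at 16.5% ± 0.3 with Srrm4 siRNA and 15.9% ± 1.1 in non-targeting libraries, which the test did not call (log2 odds ratio 0.06, adjusted p = 0.848). The rare Eif4g3.e3 fell from 0.7% ± 0.1 to 0.1% ± 0.0, on 1 of 2111 and 2 of 1852 reads (adjusted p = 0.00121). Vav2.E1 was not tested because non-targeting replicate 1 held 18 reads of it. Its PSI was 6.56% (95% Wilson interval 2.6 to 15.7) in Srrm4 replicate 1 and 8.26% (3.3 to 19.2) in replicate 2. Non-targeting replicate 1 had 80.06% (57.2 to 92.3) and replicate 2 had 71.27% (56.8 to 82.4).

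Over all target events tested with Srrm4 siRNA, 19 of 63 were called lower and 6 higher. Lists as short as those below do not show that a function was favoured. By gene list, 4 of 5 target events of the kinase and phosphatase list fell with Srrm4 siRNA, among them Mapk8.E1 and Ppp3cb.E1 (4 adjusted over the list alone). Both tested events of the vesicle traffic list fell, Kif1b.E1 and Madd.E1 (2 adjusted over the list alone), the latter in the gene of a Rab activator. In the transcription list Mef2d.E1 fell and Phf21a.E2 rose (1 each way adjusted over the list alone), in the synapse list Dlg1.E2 rose (1 adjusted over the list alone), and neither of the 2 tested RNA-processing events was called by limma (0 adjusted over the list alone).

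Srrm3 siRNA lowered 12 of 77 events and raised 1, Mapk8.e2, which shares its amplicon's reads with the lowered Mapk8.E1. Srrm3 is a paralogue of Srrm4 that is also expressed in neurons. Clasp2.E1 fell from 61.6% ± 0.1 to 27.7% ± 4.3 (log2 odds ratio -2.07, SE 0.23, adjusted p = 1.3e-07), Mef2d.E1 from 88.2% ± 1.9 to 66.5% ± 3.0 (log2 odds ratio -1.92, SE 0.23, adjusted p = 3.4e-07), and Kif1b.E1 from 92.5% ± 1.9 to 74.8% ± 1.1 (log2 odds ratio -2.08, SE 0.33, adjusted p = 1.8e-05). Mast2.E1, in a kinase gene, fell from 32.4% ± 0.2 to 10.5% ± 0.5, Acbd5.E1 from 44.5% ± 1.2 to 21.4% ± 0.3 and Asph.E1 from 40.8% ± 2.2 to 19.9% ± 0.8. Zdhhc20.E1, in a palmitoyltransferase gene, fell from 10.6% ± 0.2 to 3.5% ± 0.3, and Acap2.E1 from 99.1% ± 0.1 to 97.2% ± 0.4, a call lost against the groups with the same i5 barcodes (log2 odds ratio -0.20). Dock4.E1 fell from 56.3% ± 7.2 to 27.1% ± 2.3, Mapk8.E1 from 49.8% ± 0.0 to 37.3% ± 0.3 and Senp6.E1 from 97.5% ± 0.7 to 92.2% ± 2.5, and Mapk8.e2 rose from 50.9% ± 0.7 to 63.4% ± 2.2. Eif4g3.e3 fell from 0.7% ± 0.1 to 0.2% ± 0.2, while Eif4g3.E2 stood at 13.7% ± 0.6 against 15.9% ± 1.1 and was not called (adjusted p = 0.581). Vav2.E1, not tested, was at 51.92% (95% Wilson interval 36.8 to 66.7) and 34.78% (18.8 to 55.1). In the kinase list 2 of 5 events fell (3 adjusted over the list alone), against 11 of 63 target events tested.

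Several calls with Srrm3 siRNA were lost when 1 library was left out. The Dock4.E1 call was lost without Srrm3 replicate 1 (log2 odds ratio -1.66), Srrm3 replicate 2 (-1.90) or non-targeting replicate 2 (-1.48). Without Srrm3 replicate 2 the calls of Mapk8.E1 (-0.72), Mapk8.e2 (0.64) and Senp6.E1 (-1.33) were lost, and that of Mapk8.e2 also without non-targeting replicate 2 (0.71). The Eif4g3.e3 call was lost without Srrm3 replicate 1 (-0.92), non-targeting replicate 1 (-1.97) or non-targeting replicate 2 (-2.35). Fitted on only the groups compared, Mapk8.E1 (-0.74), Mapk8.e2 (0.74), Senp6.E1 (-1.69) and Eif4g3.e3 (-2.16) were not called. Against the groups with the same i5 barcodes the Dock4.E1 call was lost (-0.78) and Senp6.E1 lay at 0.04. That reference includes the Srrm4 and Rnps1 libraries, in which Dock4.E1, Senp6.E1 and Acap2.E1 also fell.

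Knockdown of Srrm4 and Srrm3 together gave the lowest inclusion of these exons among the 3 Srrm groups. Kif1b.E1 was at 6.8% ± 0.2 (log2 odds ratio -7.41, SE 0.33, adjusted p = 2.1e-17 against non-targeting), Clasp2.E1 at 0.7% ± 0.0 (log2 odds ratio -7.88, SE 0.23, adjusted p = 1.1e-21) and Mef2d.E1 at 28.8% ± 1.4 (log2 odds ratio -4.22, SE 0.23, adjusted p = 2.3e-15). Acap2.E1 fell to 39.7% ± 0.6, Senp6.E1 to 42.2% ± 3.3, Herc4.E1 to 24.9% ± 3.3 and Mon2.E1 to 46.3% ± 2.8. Sft2d1.E1, in a gene of vesicle transport, fell from 98.9% ± 1.6 to 49.5% ± 8.4. Dock4.E1 fell to 5.8% ± 2.1, Acbd5.E1 to 2.3% ± 0.3, Asph.E1 to 2.8% ± 0.9 and Ppp3cb.E1 to 57.1% ± 0.9. Eif4g3.e3 had 0 of 2284 and 0 of 2830 reads in the 2 libraries, which allow shares of up to 0.131% and 0.106%. Eif4g3.E2 stood at 13.4% ± 1.9 and was not called (adjusted p = 0.317). Vav2.E1, not tested, was at 7.02% (95% Wilson interval 2.8 to 16.7) and 3.82% (1.2 to 11.5).

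With the double knockdown 33 of 79 events were called, 23 lower and 10 higher. Mapk8.e2 rose to 84.4% ± 1.0, Numa1.E1 to 92.6% ± 3.4, Sgce.E1 to 73.3% ± 0.1 and Dlg1.E2 to 5.7% ± 0.7. Gse1.E2, in the gene of a subunit of a histone demethylase complex, rose from 74.3% ± 5.1 to 95.8% ± 5.9 and its overlapping event Gse1.e1 from 73.6% ± 4.7 to 95.7% ± 6.1. Gatad2a.E1, in the gene of a subunit of the NuRD complex, rose from 69.5% ± 6.9 to 84.6% ± 0.9 and Gatad2a.e2 from 69.2% ± 6.4 to 84.6% ± 0.7. Dennd5a.E1 rose to 86.3% ± 4.3 and Cit.E1 to 12.3% ± 1.0. In the lists, 4 of 5 kinase events and both vesicle traffic events fell, with the same counts when adjusted over the list alone. Of all target events tested, 22 of 64 were called lower. Without double-knockdown replicate 2 the calls of Gse1.e1 (log2 odds ratio 1.84), Gse1.E2 (1.84) and Dennd5a.E1 (0.88) were lost, and without non-targeting replicate 1 those of Gatad2a.E1 (0.92), Gatad2a.e2 (0.96) and Dennd5a.E1 (0.77). The calls of Cit.E1 (1.22) and Dennd5a.E1 (0.57) were lost with untreated as the control, that of Dennd5a.E1 also with the mean of both controls (0.91) and with at least 1 read (1.25), and those of Gse1.e1 (3.54), Gse1.E2 (3.52) and Dennd5a.E1 (1.25) in a fit on only the groups compared.

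**Figure D1:**
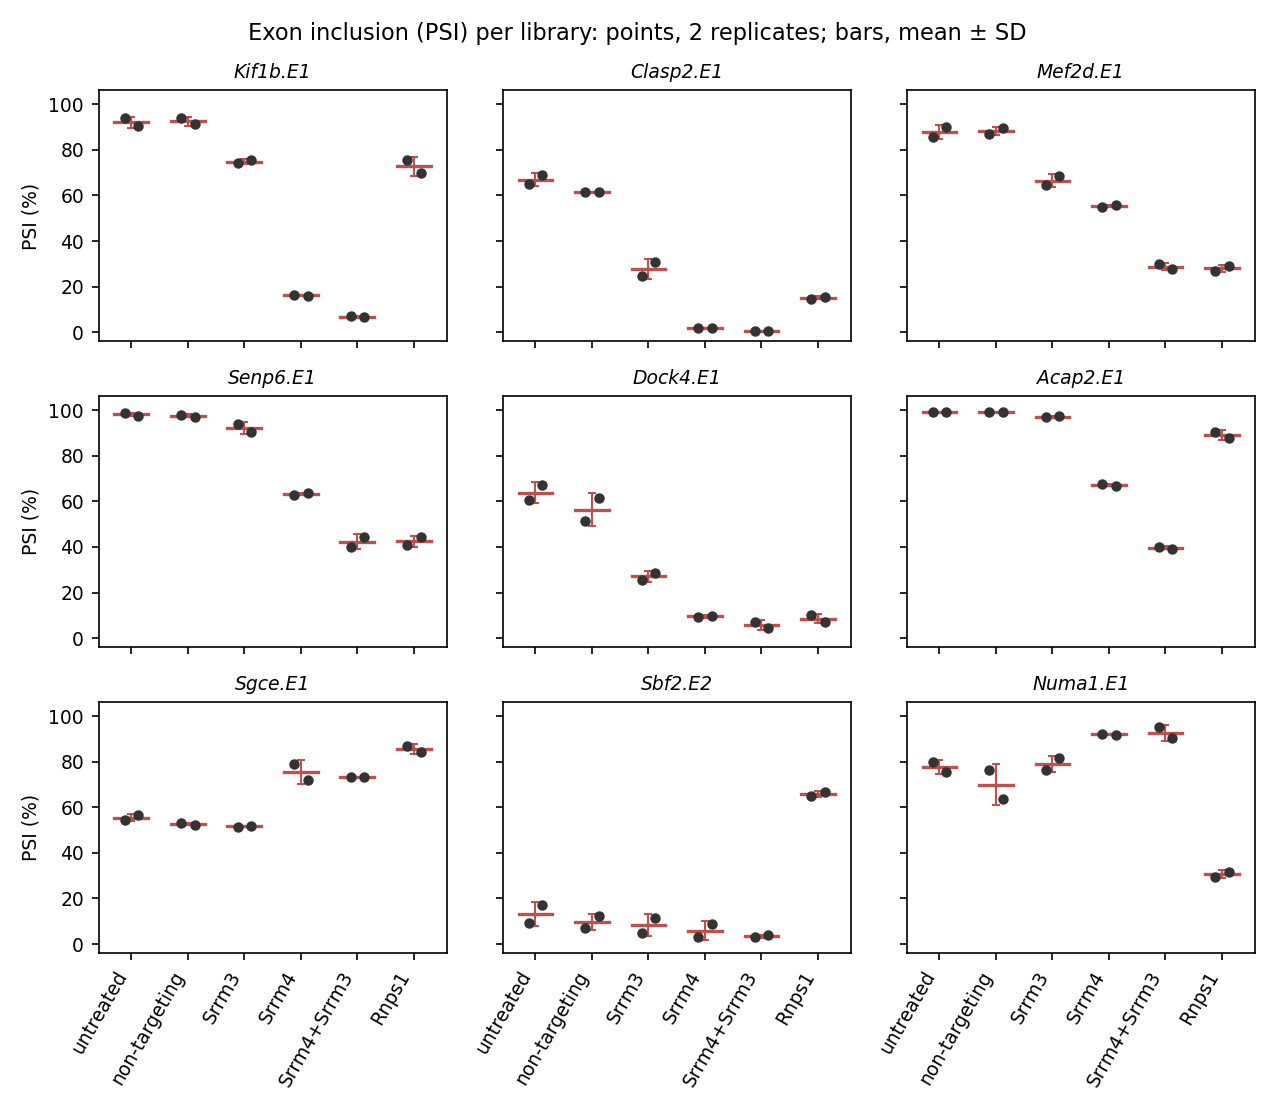
PSI in percent of 9 target events in untreated, non-targeting, Srrm3, Srrm4, double and Rnps1 siRNA libraries; points are the 2 libraries of a group and red bars the mean ± SD. Kif1b.E1 lay at 92.5% in non-targeting and 6.8% in double-knockdown libraries, and Sbf2.E2 at 65.8% in Rnps1 libraries against 9.7% in non-targeting ones.

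Inclusion was lower with both siRNAs than with Srrm4 siRNA alone in 13 of 80 events and higher in none. Acap2.E1 fell from 67.1% ± 0.4 to 39.7% ± 0.6 (log2 odds ratio -1.63, SE 0.37, adjusted p = 0.00176) and Mef2d.E1 from 55.3% ± 0.4 to 28.8% ± 1.4 (log2 odds ratio -1.62, SE 0.23, adjusted p = 1.8e-05). Senp6.E1 fell from 63.3% ± 0.5 to 42.2% ± 3.3, a call that was lost whichever library was left out (log2 odds ratio -1.26 without Srrm4 replicate 1, -1.22 without Srrm4 replicate 2, -1.10 without double-knockdown replicate 1 and -1.37 without double-knockdown replicate 2). These 3 events were the only called ones that differed by 10 points or more. The count was 8 without Srrm4 replicate 2. The double-knockdown libraries lay in the other row of i5 barcodes than the Srrm4 and Srrm3 libraries, so the row is not separated from the added siRNA here, in the comparison with Srrm3 or in the interaction.

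Against Srrm3 siRNA alone, 28 of 79 events were called with both siRNAs, 22 lower and 6 higher. Kif1b.E1 fell from 74.8% ± 1.1 to 6.8% ± 0.2 (log2 odds ratio -5.33, SE 0.33, adjusted p = 7.8e-14), Acap2.E1 from 97.2% ± 0.4 to 39.7% ± 0.6 and Herc4.E1 from 81.1% ± 4.0 to 24.9% ± 3.3. Sgce.E1 rose from 51.7% ± 0.3 to 73.3% ± 0.1 and Mapk8.e2 from 63.4% ± 2.2 to 84.4% ± 1.0. Gse1.e1 rose from 76.7% ± 3.2 to 95.7% ± 6.1, a call lost without Srrm3 replicate 1 (log2 odds ratio 3.14), without double-knockdown replicate 2 (1.61) and in a fit on only the groups compared (3.31). For the interaction of the knockdowns on the log odds scale, limma called 0 of 74 events, with 2 at an unadjusted p under 0.05 (Ubr4.E1, log2 odds ratio -2.79, adjusted p = 0.178, and Zdhhc20.E1, log2 odds ratio 0.70, adjusted p = 0.952), and no other tool was run on it. The interaction estimate was 0.31 with SE 0.33 for Mef2d.E1 and -0.04 with SE 0.52 for Acap2.E1.

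The amplicons of both targets took a smaller share of reads with their own siRNA. The Srrm4 amplicon fell from 29.5 ± 6.61 to 7.86 ± 1.29 reads per 10000 with Srrm4 siRNA (log2 change -1.88, SE 0.22, adjusted p = 1.1e-07) and to 5.46 ± 0.236 with both siRNAs (log2 change -2.40, adjusted p = 5.5e-10). The Srrm3 amplicon fell from 13.5 ± 0.159 to 4.65 ± 1.22 with Srrm3 siRNA (log2 change -1.54, SE 0.32, adjusted p = 0.00368), a call lost without Srrm3 replicate 2 (log2 change -1.28), and to 4.87 ± 0.492 with both siRNAs (log2 change -1.46, adjusted p = 6.0e-04). With Srrm4 siRNA alone the Srrm3 amplicon took 9.51 ± 2.73, against 20.4 ± 0.316 in untreated libraries. Against non-targeting it was not called (log2 change -0.53, SE 0.32, limma adjusted p = 0.184), so a fall of Srrm3 is not excluded. The Srrm4 share was lower with both siRNAs than with Srrm4 siRNA alone, and no test of that is given. Differences between these 2 groups therefore need not come from Srrm3 alone. Amplicons of the other siRNA targets were not on the panel.

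Rnps1 siRNA lowered inclusion of many of the exons that fell with Srrm4 siRNA. Rnps1 is an SR-related protein that associates with the exon junction complex. Mef2d.E1 fell from 88.2% ± 1.9 to 28.1% ± 1.5 (log2 odds ratio -4.27, SE 0.23, adjusted p = 9.5e-15), Senp6.E1 from 97.5% ± 0.7 to 42.5% ± 2.5 (log2 odds ratio -5.70, SE 0.39, adjusted p = 9.7e-13), and Clasp2.E1 from 61.6% ± 0.1 to 15.1% ± 0.6 (log2 odds ratio -3.17, SE 0.23, adjusted p = 3.3e-12). Sbf2.E2, in the gene of a myotubularin-related protein, rose from 9.7% ± 3.5 to 65.8% ± 1.2 (log2 odds ratio 4.16, SE 0.48, adjusted p = 1.6e-08). In all, 41 of 75 events were called, 31 lower and 10 higher, 34 of them by 10 points or more.

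Among the other exons that fell with Rnps1 siRNA, Dock4.E1 reached 8.6% ± 2.0 and Mast2.E1 4.4% ± 0.7. Ptbp2.E1, in the gene of the neuronal polypyrimidine tract binding protein, fell from 66.8% ± 1.1 to 19.3% ± 4.0. Csnk1g3.E1, in a casein kinase gene, fell from 90.3% ± 0.7 to 49.6% ± 5.2, Numa1.E1 from 69.8% ± 9.0 to 30.7% ± 1.6, and Dtnb.E2, in the beta-dystrobrevin gene, from 71.0% ± 0.3 to 32.3% ± 1.6. The event 2410002O22Rik.E1, in the gene now named Trappc13, fell from 50.9% ± 0.4 to 15.0% ± 0.0. Kifc3.E1, in a kinesin gene, fell from 88.0% ± 8.1 to 58.4% ± 6.8 and Pacsin2.E1, in the gene of a membrane-bending protein, from 61.3% ± 2.8 to 33.8% ± 1.7. Eif4g3.E2 fell from 15.9% ± 1.1 to 7.7% ± 0.6 (adjusted p = 1.1e-04) and Eif4g3.e3 from 0.7% ± 0.1 to 0.2% ± 0.0. Vav2.E1, not tested, was at 31.25% (95% Wilson interval 14.2 to 55.6) and 27.43% (13 to 48.8). In the lists, 3 of 4 kinase events and both RNA-processing events fell, with the same counts when adjusted over the list alone. Of all target events tested, 28 of 61 were called lower, so these short lists do not show that a function was favoured.

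Inclusion rose with Rnps1 siRNA in Sgce.E1, to 85.6% ± 2.0, and in Atp9b.E1, in the gene of a lipid flippase, from 43.9% ± 5.2 to 76.2% ± 15.1, a call lost in a fit on only the groups compared (log2 odds ratio 2.11). Mapk8.e2 rose to 78.8% ± 0.2, Gse1.E2 to 98.6% ± 2.0, Gse1.e1 to 98.5% ± 2.1, Gatad2a.E1 to 90.8% ± 0.4 and Gatad2a.e2 to 88.1% ± 0.4. Rbm26.E2, in the gene of an RNA-binding protein, rose from 89.8% ± 0.6 to 94.8% ± 1.0 and Dlg1.E2 from 0.3% ± 0.1 to 1.2% ± 0.3. The calls of Pacsin2.E1 and Eif4g3.e3 were lost whichever library was left out (log2 odds ratios -1.68 and -1.67 without Rnps1 replicate 1, -1.53 and -1.82 without Rnps1 replicate 2, -1.73 and -1.55 without non-targeting replicate 1, and -1.48 and -1.93 without non-targeting replicate 2). The Rbm26.E2 call was lost without Rnps1 replicate 1 (0.84) or non-targeting replicate 1 (0.97), and that of Kifc3.E1 without non-targeting replicate 1 (-1.71), in a fit on only the groups compared (-2.54) and against the groups with the same i5 barcodes (-1.03). Against those groups Dlg1.E2 (0.54) and Eif4g3.e3 (-1.13) were not called either.

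Events that fell with both Rnps1 and Srrm4 siRNA numbered 15 of the 74 tested in both. Among these 74 events, 30 were lower with Rnps1 and 20 with Srrm4 siRNA, for which 8.1 shared events are expected by chance if the lists are independent. The 15 events included Kif1b.E1, Clasp2.E1, Dock4.E1, Mef2d.E1, Senp6.E1, Acap2.E1 and Ppp3cb.E1. Several of them were called in many of the 22 knockdowns, Senp6.E1 lower in 10 and higher in 1, Clasp2.E1 in 9 and 6, and Mef2d.E1 in 9 and 8. The lists of other pairs of knockdowns may therefore also overlap more than independent lists would. Of 10 and 7 higher events, 3 were shared (Sgce.E1, Mapk8.e2 and Dlg1.E2, with 0.9 expected). Mapk8.e2 shares reads with Mapk8.E1, which is among the 15 lower events, so this amplicon counts in both tallies. The expected numbers treat such events as independent. Numa1.E1 was called in opposite directions, lower with Rnps1 and higher with Srrm4 siRNA. Ptbp2.E1 and Sbf2.E2 were called with Rnps1 siRNA and not with Srrm4 siRNA, where they differed from the control by -1.0 and -3.9 points. The difference between the knockdowns was not tested. With untreated libraries as the control of Rnps1 or of Srrm4, 15 and 16 lower events were shared.

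**Figure D2:**
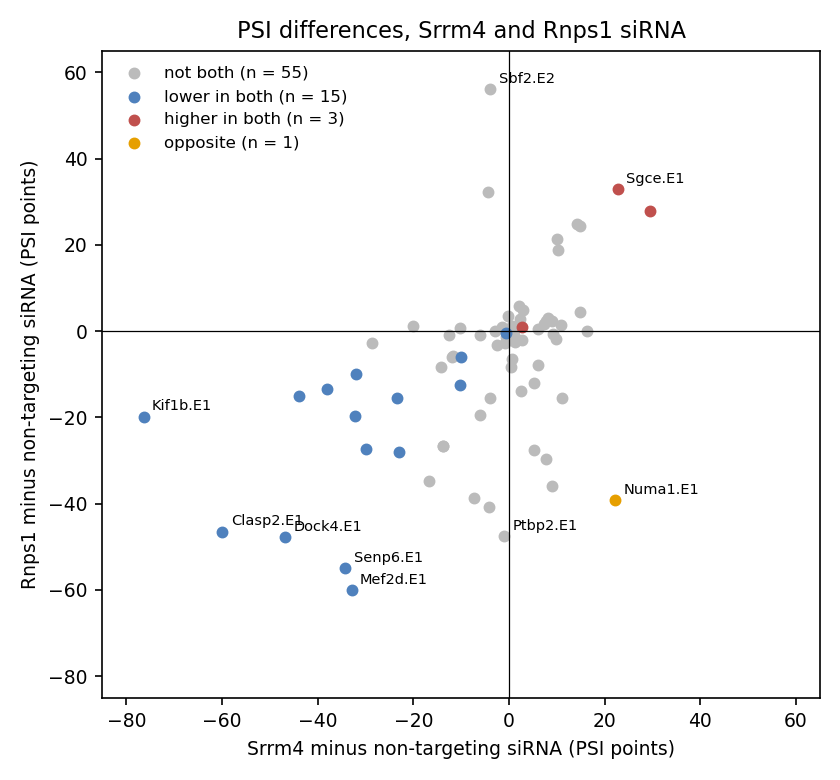
PSI differences from non-targeting libraries in points for the events tested in both comparisons, Srrm4 siRNA on the x axis and Rnps1 siRNA on the y axis; colours mark events called in both. The 15 blue points fell in both knockdowns and 1 point, Numa1.E1, went in opposite directions.

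Over all 22 knockdowns, 520 of 1739 pairs of event and knockdown were called, 301 lower and 219 higher, and 399 of them by 10 points or more. Against untreated libraries 346 were lower and 221 higher, and against the mean of both controls 358 were lower and 261 higher. Lower events thus outnumbered higher ones with each control. Against the groups with the same i5 barcodes 320 were lower and 375 higher. That reference averages mostly other knockdowns, which draws the balance towards even, so it cannot show that the balance depends on the control. Mapk8.E1 was called in 17 knockdowns, higher in 9 and lower in 8, with differences from -34.0 points in double-knockdown to 35.2 points in Ptbp1 libraries. Mef2d.E1 was also called in 17, lower in 9 and higher in 8, and its lowest and highest differences were -60.1 points with Rnps1 and 9.9 points with Ptbp1 siRNA. By class, 126 of 318 pairs were called with siRNA against core spliceosome, cap-binding and G-patch proteins (60 higher, 66 lower) and 166 of 551 with siRNA against sequence-specific RNA-binding proteins (65 higher, 101 lower). Strbp, a double-stranded RNA binding protein, was counted in the latter class, so that name does not hold for all its members. For the chromatin and acetyltransferase proteins 37 of 241 pairs were called (21 higher, 16 lower), and for the SR and exon junction factors 67 of 155 (20 higher, 47 lower). The Srrm groups gave 74 of 233 (18 higher, 56 lower) and the class of other proteins 50 of 241 (35 higher, 15 lower). Single siRNAs weighed heavily in these counts. Ep300 gave 25 of the 37 chromatin calls and CBP and Hira 6 each, and Ippk gave 28 of the 50 others, Fam133b 22 and Fbxw11 0. Depletion was checked only for Srrm4 and Srrm3, so few or no calls, as with Fxr1 and Fbxw11, cannot be told from weak knockdown.

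**Figure D3:**
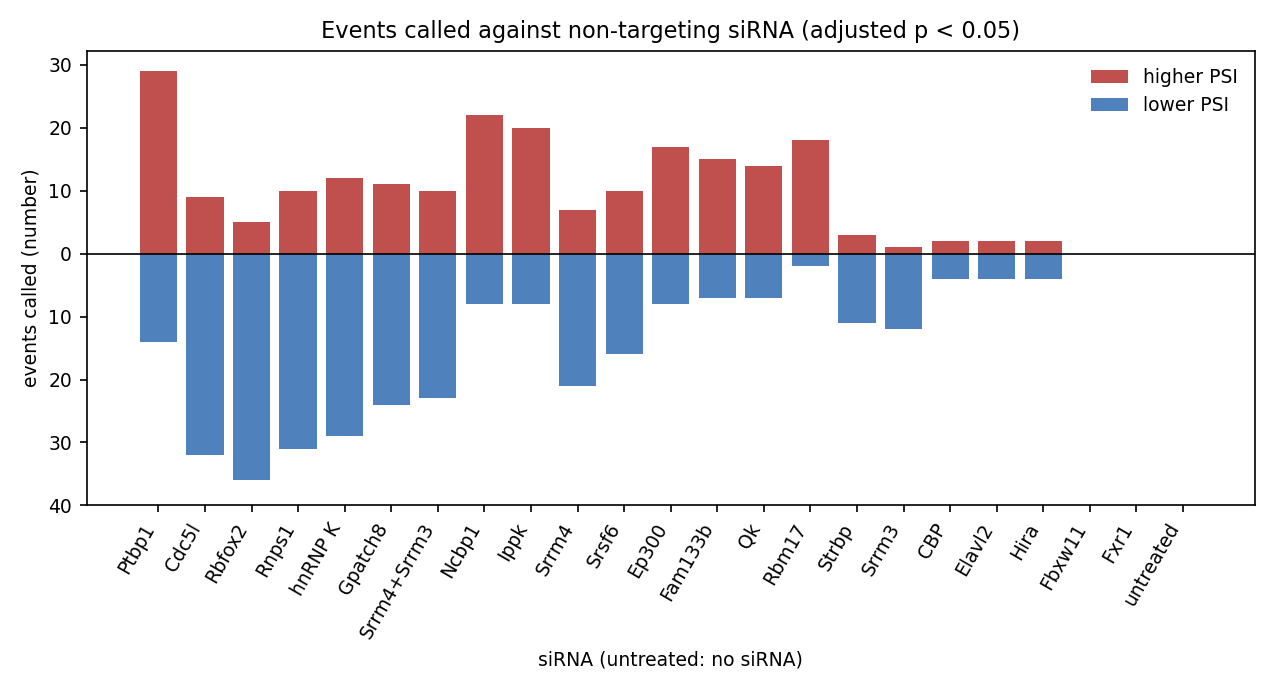
Number of events called against non-targeting siRNA at an adjusted p under 0.05 in each of the 22 knockdowns and in untreated cells, with higher PSI drawn upwards and lower PSI downwards from 0. Ptbp1 siRNA gave 29 higher events and Rbfox2 siRNA 36 lower ones.

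Ptbp1, a repressor of neuronal exons, gave the screen's largest rises when knocked down. Pbrm1.E2, in the gene of a subunit of a chromatin remodelling complex, rose from 4.0% ± 1.4 to 92.2% ± 5.8 (log2 odds ratio 8.13, SE 0.55, adjusted p = 6.2e-13). The event 1700021K19Rik.E1, in the gene now named Rubcn that acts in autophagy, rose from 13.4% ± 1.6 to 92.5% ± 1.1, and Col4a3bp.E1, in the ceramide transfer protein gene, from 17.2% ± 1.6 to 87.8% ± 1.9. Abi2.E1, in the gene of a subunit of the actin-regulating WAVE complex, fell from 92.3% ± 10.9 to 13% ± 6.1 (adjusted p = 2.7e-06). Ddhd1.E1, in a phospholipase gene, fell from 78.6% ± 5.7 to 16.2% ± 1.3 and Ddhd1.e2 from 78.5% ± 5.5 to 16.3% ± 0.8. In all, 43 of 80 events were called, 29 higher and 14 lower.

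Rbfox2 binds UGCAUG motifs beside neural and muscle exons, and 36 of the 41 events called with its siRNA (of 76) fell. Dtnb.E2 fell from 71.0% ± 0.3 to 1.2% ± 0.2 (log2 odds ratio -7.59, SE 0.20, adjusted p = 4.0e-23), Csnk1g3.E1 from 90.3% ± 0.7 to 14.5% ± 5.7 and Numa1.E1 from 69.8% ± 9.0 to 3.9% ± 0.7. Sbf2.E2 rose from 9.7% ± 3.5 to 26.8% ± 5.5, a call lost without non-targeting replicate 1 (log2 odds ratio 1.38). Gse1.E2 rose from 74.3% ± 5.1 to 94.1% ± 5.8 and Gse1.e1 from 73.6% ± 4.7 to 94.0% ± 6.0, calls lost without Rbfox2 replicate 1 (1.53 and 1.54), non-targeting replicate 1 (2.37 and 2.40) or non-targeting replicate 2 (2.90 and 2.88), that of Gse1.e1 also with at least 1 read (2.64). The count was 26 without Rbfox2 replicate 2.

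With siRNA against hnRNP K, a protein that binds C-rich RNA, 41 of 81 events were called, 29 lower and 12 higher. Gatad2a.E1 fell from 69.5% ± 6.9 to 7.6% ± 1.4 (log2 odds ratio -4.80, SE 0.36, adjusted p = 8.4e-12), together with Gatad2a.e2, from 69.2% ± 6.4 to 7.5% ± 1.8, and Kifc3.E1 fell from 88.0% ± 8.1 to 39.3% ± 2.4. Evl.E1, in the gene of an actin-binding Ena/VASP protein, rose from 22.7% ± 0.2 to 67.7% ± 2.7, Syne2.E1, in the gene of the nuclear envelope protein nesprin-2, from 28.6% ± 1.4 to 65.9% ± 1.7, and Pacsin2.E1 from 61.3% ± 2.8 to 98.0% ± 2.8. Evl.E1 went the other way with siRNA against Qk, an RNA-binding protein of the STAR family, from 22.7% ± 0.2 to 0.7% ± 0.2 (log2 odds ratio -5.26, SE 0.36, adjusted p = 2.6e-12). The test called 21 of 78 events with Qk siRNA, 14 higher and 7 lower. Asph.E1 rose from 40.8% ± 2.2 to 75.7% ± 3.7, Atp9b.E1 from 43.9% ± 5.2 to 76.0% ± 6.0 and Acbd5.E1 from 44.5% ± 1.2 to 73.5% ± 4.5. The event 2410002O22Rik.E1 fell from 50.9% ± 0.4 to 23.5% ± 1.3, and Dennd5a.E1 from 72.2% ± 9.6 to 43.5% ± 0.8, a call lost without Qk replicate 2 (log2 odds ratio -1.73) or non-targeting replicate 2 (-1.28).

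With siRNA against Strbp, a double-stranded RNA binding protein, 14 of 78 events were called, 11 lower and 3 higher. Atp13a3.E1, in the gene of a P-type ATPase, fell from 37.0% ± 4.4 to 11.6% ± 4.0 (log2 odds ratio -2.19, SE 0.32, adjusted p = 8.0e-06) and Atp9b.E1 from 43.9% ± 5.2 to 22.3% ± 9.0. Mapk8.e2 rose from 50.9% ± 0.7 to 65.5% ± 0.3, Dennd5a.E1 from 72.2% ± 9.6 to 89.6% ± 7.4 and Dlg1.E2 from 0.3% ± 0.1 to 1.1% ± 0.4. Without Strbp replicate 1 the count was 9 and the calls of Atp9b.E1 (-0.94), Dennd5a.E1 (0.98) and Dlg1.E2 (1.76) were lost, that of Dennd5a.E1 also without non-targeting replicate 1 (1.36), and those of Atp9b.E1 (-1.26) and Dlg1.E2 (1.6) without non-targeting replicate 2. Against untreated the calls of Dennd5a.E1 (1.16) and Dlg1.E2 (1.32) were lost, and against the groups with the same i5 barcodes that of Dlg1.E2 (0.37). The Atp9b.E1 call was also lost with at least 1 read (-1.47). A fit on only the groups compared called 1 event, none of these 5: Atp13a3.E1 (-2.19), Atp9b.E1 (-1.47), Mapk8.e2 (0.87), Dennd5a.E1 (1.84) and Dlg1.E2 (2.12) were not called in it.

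Elavl2, a neuronal Hu protein, gave 6 calls of 81, 4 lower and 2 higher. Sgce.E1 rose from 52.6% ± 0.6 to 67.3% ± 0.9 (adjusted p = 0.00717) and Itpr1.E1, in the gene of an inositol trisphosphate receptor, from 33.4% ± 2.7 to 55.7% ± 3.0. Clasp2.E1 fell from 61.6% ± 0.1 to 46.7% ± 1.1, Zdhhc20.E1 from 10.6% ± 0.2 to 5.8% ± 0.1 and Fam168a.E1 from 15.9% ± 12.9 to 1.3% ± 1.8. No event was called by limma without Elavl2 replicate 1, Elavl2 replicate 2 or non-targeting replicate 1, with the log2 odds ratio of Sgce.E1 at 0.85, 0.93 and 0.92, of Itpr1.E1 at 1.43, 1.18 and 1.18, of Clasp2.E1 at -0.92, -0.83 and -0.87, of Zdhhc20.E1 at -0.93, -0.96 and -0.92 and of Fam168a.E1 at -3.04, -2.10 and -1.54. Without non-targeting replicate 2 the calls of Itpr1.E1 (1.42) and Clasp2.E1 (-0.88) were lost. Against the groups with the same i5 barcodes Clasp2.E1 lay at 0.50 and Zdhhc20.E1 at 0.01, the reverse direction, and the Itpr1.E1 call was lost (0.57), as it was against untreated (1.05). That reference includes the Srrm4 and Rnps1 libraries, where Clasp2.E1 fell by 59.9 and 46.5 points and Zdhhc20.E1 by 10.1 and 6.1. The reversed signs therefore cannot tell an unstable Elavl2 effect from a lowered reference. With at least 1 read the calls of Fam168a.E1 (-2.57) and Itpr1.E1 (1.30) were lost. None was called in a fit on only the groups compared, with Sgce.E1 at 0.89, Itpr1.E1 at 1.30, Clasp2.E1 at -0.88, Zdhhc20.E1 at -0.95 and Fam168a.E1 at -2.57, while 18 were called by the quasi-binomial test, and 22 events had an unadjusted p under 0.05. For siRNA against Fxr1, a relative of the fragile X protein, limma called 0 of 77 events, with 9 at an unadjusted p under 0.05, and the quasi-binomial test called 4 and limma with a replicate block 2. Dtnb.E2 was at 59.3% ± 1.0 against 71.0% ± 0.3 (adjusted p = 0.0615) and Clasp2.E1 at 73.1% ± 1.5 against 61.6% ± 0.1 (adjusted p = 0.118).

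Cdc5l, a component of the spliceosome's Prp19 complex, gave 41 calls of 79 when knocked down, 32 lower and 9 higher. Ktn1.E1, in the kinectin gene, fell from 72.0% ± 0.8 to 13.9% ± 10.4, Kifc3.E1 from 88.0% ± 8.1 to 32.3% ± 3.1 and Ddhd1.E1 from 78.6% ± 5.7 to 30.9% ± 0.1. Mapk8.E1 rose from 49.8% ± 0.0 to 84.9% ± 2.6 (log2 odds ratio 2.50, SE 0.20, adjusted p = 9.7e-12), Itpr1.E1 from 33.4% ± 2.7 to 73.2% ± 3.8 and Atp9b.E1 from 43.9% ± 5.2 to 73.0% ± 6.7. With siRNA against Gpatch8, a G-patch protein, 35 of 81 events were called, 24 lower and 11 higher. Kifc3.E1 fell to 40.1% ± 9.0, Dtnb.E2 from 71.0% ± 0.3 to 29.1% ± 0.1 (log2 odds ratio -2.58, SE 0.20, adjusted p = 3.2e-11) and 2410002O22Rik.E1 from 50.9% ± 0.4 to 10.3% ± 4.2. Tnik.E1, in a kinase gene, rose from 36.3% ± 4.8 to 69.7% ± 2.1, Col4a3bp.E1 from 17.2% ± 1.6 to 38.3% ± 5.7 and Itpr1.E1 to 55.8% ± 5.7. The Gpatch8 count was 20 and 16 without its replicates 1 and 2, 19 and 23 without non-targeting replicates 1 and 2, and 18 in a fit on only the groups compared. Its Itpr1.E1 call was lost without Gpatch8 replicate 1 (1.08), without non-targeting replicate 1 (1.19) and against the groups with the same i5 barcodes (0.57).

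Knockdown of Ncbp1, the large subunit of the nuclear cap-binding complex, raised more events than it lowered, 22 and 8 of 80. Dennd5a.E1 rose from 72.2% ± 9.6 to 95.6% ± 1.1 (log2 odds ratio 2.86, SE 0.50, adjusted p = 6.4e-05), Asph.E1 from 40.8% ± 2.2 to 66.5% ± 12.2 and Gse1.e1 from 73.6% ± 4.7 to 96.6% ± 1.3. Ddhd1.E1 fell from 78.6% ± 5.7 to 28.7% ± 7.9, Ddhd1.e2 from 78.5% ± 5.5 to 29.3% ± 2.6 and Ktn1.E1 from 72.0% ± 0.8 to 33.3% ± 16.2. The Ncbp1 count was 12 without Ncbp1 replicate 1, 13 without non-targeting replicate 1 and 15 in a fit on only the groups compared. The Ktn1.E1 call was lost without Ncbp1 replicate 1 (log2 odds ratio -3.12), Ncbp1 replicate 2 (-1.61), non-targeting replicate 1 (-2.34) or non-targeting replicate 2 (-2.39), against the groups with the same i5 barcodes (-1.27) and with at least 1 read (-2.37), that of Gse1.e1 without Ncbp1 replicate 1 (2.85) or non-targeting replicate 1 (2.94), and that of Asph.E1 without Ncbp1 replicate 1 (0.99) and in a fit on only the groups compared (1.55). With siRNA against Rbm17, a factor of the early spliceosome, 20 of 78 events were called, 18 higher and 2 lower, and 6 in a fit on only the groups compared. Tnik.E1 rose from 36.3% ± 4.8 to 73.8% ± 4.0, Sbf2.E2 from 9.7% ± 3.5 to 46.2% ± 3.0 and Clasp2.E1 from 61.6% ± 0.1 to 89.9% ± 0.8 (log2 odds ratio 2.46, SE 0.23, adjusted p = 3.4e-09). Mapk8.E1 fell from 49.8% ± 0.0 to 26.9% ± 2.2, a call lost in the fit on only the groups compared (-1.43). Mef2d.E1 fell from 88.2% ± 1.9 to 81.1% ± 1.1, a call lost in the same fit (-0.81) and without Rbm17 replicate 1 (-0.74) or non-targeting replicate 2 (-0.63).

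Srsf6, a serine- and arginine-rich splicing factor, gave 26 calls of 80 when knocked down, 16 lower and 10 higher. Sgce.E1 rose from 52.6% ± 0.6 to 88.7% ± 2.4 (log2 odds ratio 2.84, SE 0.19, adjusted p = 2.0e-12), Gse1.E2 from 74.3% ± 5.1 to 97.8% ± 0.6 and Gse1.e1 from 73.6% ± 4.7 to 97.8% ± 0.6. Nova2.E1, in the gene of a neuronal splicing factor, fell from 62.9% ± 6.5 to 28.1% ± 5.6 and Ptbp2.E1 from 66.8% ± 1.1 to 35.1% ± 16.9. Without Srsf6 replicate 1 the count was 17 and the call of Gse1.e1 (log2 odds ratio 3.45) was lost.

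Ep300 is a histone acetyltransferase, and CBP, a name given in the labels, was taken here to be its paralogue, the CREB-binding protein. With Ep300 siRNA 25 of 80 events were called against non-targeting, 17 higher and 8 lower. Col4a3bp.E1 rose from 17.2% ± 1.6 to 52.1% ± 8.1 (log2 odds ratio 2.37, SE 0.30, adjusted p = 1.1e-06), Tnik.E1 from 36.3% ± 4.8 to 62.6% ± 1.1 and Ptbp2.E1 from 66.8% ± 1.1 to 90.1% ± 0.9. Ddhd1.E1 fell from 78.6% ± 5.7 to 34.2% ± 18.5, Ddhd1.e2 from 78.5% ± 5.5 to 34.3% ± 16.3 and Ktn1.E1 from 72.0% ± 0.8 to 25.1% ± 2.5. The Ktn1.E1 call was lost without Ep300 replicate 1 (log2 odds ratio -3.0), Ep300 replicate 2 (-2.72), non-targeting replicate 1 (-2.84) or non-targeting replicate 2 (-2.89). The Ep300 count was 16 without Ep300 replicate 2 and 15 without non-targeting replicate 2, and 53 against the groups with the same i5 barcodes.

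With CBP siRNA 6 of 81 events were called, 4 lower and 2 higher. Sh3pxd2a.E1, in the gene of a podosome scaffold, fell from 24.4% ± 1.8 to 9.3% ± 0.1 (adjusted p = 0.00741), Kifc3.E1 from 88.0% ± 8.1 to 58.7% ± 13.8 and Camk2a.E1, in the gene of a calcium-dependent kinase, from 28.1% ± 16 to 6.6% ± 3.0. Clasp2.E1 rose from 61.6% ± 0.1 to 74.7% ± 2.1 and Mef2d.E1 from 88.2% ± 1.9 to 93.7% ± 0.8. Limma called none of them without CBP replicate 2 or non-targeting replicate 1, with log2 odds ratios of -1.65 and -1.54 for Sh3pxd2a.E1, -1.91 and -1.68 for Kifc3.E1, -2.70 and -1.44 for Camk2a.E1, 0.99 and 0.88 for Clasp2.E1 and 0.86 and 0.81 for Mef2d.E1. Without CBP replicate 1 the calls of Camk2a.E1 (-1.83) and Clasp2.E1 (0.76) were lost, and without non-targeting replicate 2 that of Clasp2.E1 (0.87). The Clasp2.E1 call was also lost against untreated (0.54) and that of Sh3pxd2a.E1 against the groups with the same i5 barcodes (-0.53), and with at least 1 read that of Camk2a.E1 (-2.27). None was called in a fit on only the groups compared, with Sh3pxd2a.E1 at -1.64, Kifc3.E1 at -2.50, Camk2a.E1 at -2.27, Clasp2.E1 at 0.88 and Mef2d.E1 at 1.00, while the quasi-binomial test called 17 and 18 events had an unadjusted p under 0.05.

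Compared directly, Ep300 and CBP libraries differed in 29 of 83 events, 20 higher and 9 lower with Ep300 siRNA. Col4a3bp.E1 was at 52.1% ± 8.1 with Ep300 and 15.2% ± 3.7 with CBP siRNA (log2 odds ratio 2.61, SE 0.30, adjusted p = 8.7e-08), and Lsm14b.E1, in the gene of an RNA-binding protein of translational control, at 46.0% ± 12 and 18.5% ± 0.9. Numa1.E1 was at 75.2% ± 7.9 and 42.7% ± 4.5, a call lost without Ep300 replicate 1 (log2 odds ratio 1.61). Ddhd1.E1 was at 34.2% ± 18.5 with Ep300 and 66.5% ± 3.8 with CBP siRNA, and Ddhd1.e2 at 34.3% ± 16.3 and 66.2% ± 3.6, calls lost without Ep300 replicate 2 (-1.13 and -1.19) and in a fit on only the groups compared (-1.98 and -1.93). Dock4.E1 was at 48.7% ± 2.6 and 75.5% ± 6.3, a call lost without Ep300 replicate 1 (-1.78), Ep300 replicate 2 (-1.57) or CBP replicate 2 (-1.34). Ep300 and CBP libraries lay in different rows of i5 barcodes, which this comparison does not separate from the siRNA. The count was 16 without Ep300 replicate 1, 17 with at least 100 reads and 18 in a fit on only the groups compared.

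For the histone chaperone Hira 6 of 80 events were called, 4 lower and 2 higher. Gatad2a.E1 rose from 69.5% ± 6.9 to 91.8% ± 2.7 (log2 odds ratio 2.30, SE 0.36, adjusted p = 2.9e-05) and Gatad2a.e2 from 69.2% ± 6.4 to 91.8% ± 2.6. Clasp2.E1 fell from 61.6% ± 0.1 to 46.1% ± 2.4 and Dtnb.E2 from 71.0% ± 0.3 to 58.8% ± 0.5. The Dtnb.E2 call was lost without Hira replicate 1 (log2 odds ratio -0.75), Hira replicate 2 (-0.80), non-targeting replicate 1 (-0.76) or non-targeting replicate 2 (-0.79), and that of Clasp2.E1 without Hira replicate 1 (-0.81), non-targeting replicate 1 (-0.91) or non-targeting replicate 2 (-0.91). The Hira count was 3 without non-targeting replicate 1, and a fit on only the groups compared called 1 event, none of these 4: Gatad2a.E1 (2.30), Gatad2a.e2 (2.33), Clasp2.E1 (-0.91) and Dtnb.E2 (-0.77) were not called in it.

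Knockdown of Ippk, the kinase that makes inositol hexakisphosphate, raised 20 and lowered 8 of 79 events. Mapk8.E1 rose from 49.8% ± 0.0 to 82.7% ± 0.8 (log2 odds ratio 2.26, SE 0.20, adjusted p = 2.9e-10) while Mapk8.e2 fell from 50.9% ± 0.7 to 17% ± 0.3. The event 1700021K19Rik.E1 rose from 13.4% ± 1.6 to 50.4% ± 3.9 and Itpr1.E1 from 33.4% ± 2.7 to 66.5% ± 7.5, and Kifc3.E1 fell from 88.0% ± 8.1 to 35.9% ± 9.7. Ktn1.E1 fell from 72.0% ± 0.8 to 27.8% ± 0.0, a call lost without Ippk replicate 1 (log2 odds ratio -2.66), Ippk replicate 2 (-2.65), non-targeting replicate 1 (-2.63) or non-targeting replicate 2 (-2.68) and against the groups with the same i5 barcodes (-1.58). The Ippk count was 16 without Ippk replicate 1.

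With siRNA against Fam133b 22 of 81 events were called, 15 higher and 7 lower. Mapk8.E1 rose from 49.8% ± 0.0 to 79.5% ± 2.7 (log2 odds ratio 1.97, SE 0.20, adjusted p = 4.8e-09) while Mapk8.e2 fell from 50.9% ± 0.7 to 19.8% ± 2.9. The event 1700021K19Rik.E1 rose from 13.4% ± 1.6 to 40.8% ± 1.6 and Med23.E1, in the gene of a Mediator subunit, from 23.8% ± 3.8 to 51.4% ± 7.2, a call lost without Fam133b replicate 2 (log2 odds ratio 1.46). Ddhd1.E1 fell from 78.6% ± 5.7 to 37.7% ± 20.8 and Ddhd1.e2 from 78.5% ± 5.5 to 36.6% ± 18.9. In the fit over all groups 31 events had an unadjusted p under 0.05, and the quasi-binomial test called 30. A fit of limma on only the groups compared called 0 events, with log2 odds ratios of 1.97 for Mapk8.E1, -2.08 for Mapk8.e2, 2.16 for 1700021K19Rik.E1, 1.75 for Med23.E1, -2.63 for Ddhd1.E1 and -2.67 for Ddhd1.e2. For the ubiquitin ligase subunit Fbxw11 limma called 0 of 81 events, with 12 at an unadjusted p under 0.05, the quasi-binomial test called 5, and limma called 1 without non-targeting replicate 2. Camk2a.E1 was at 6.7% ± 0.1 against 28.1% ± 16 (adjusted p = 0.17) and Mef2d.E1 at 82.4% ± 2.1 against 88.2% ± 1.9 (adjusted p = 0.201).

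**Figure D4:**
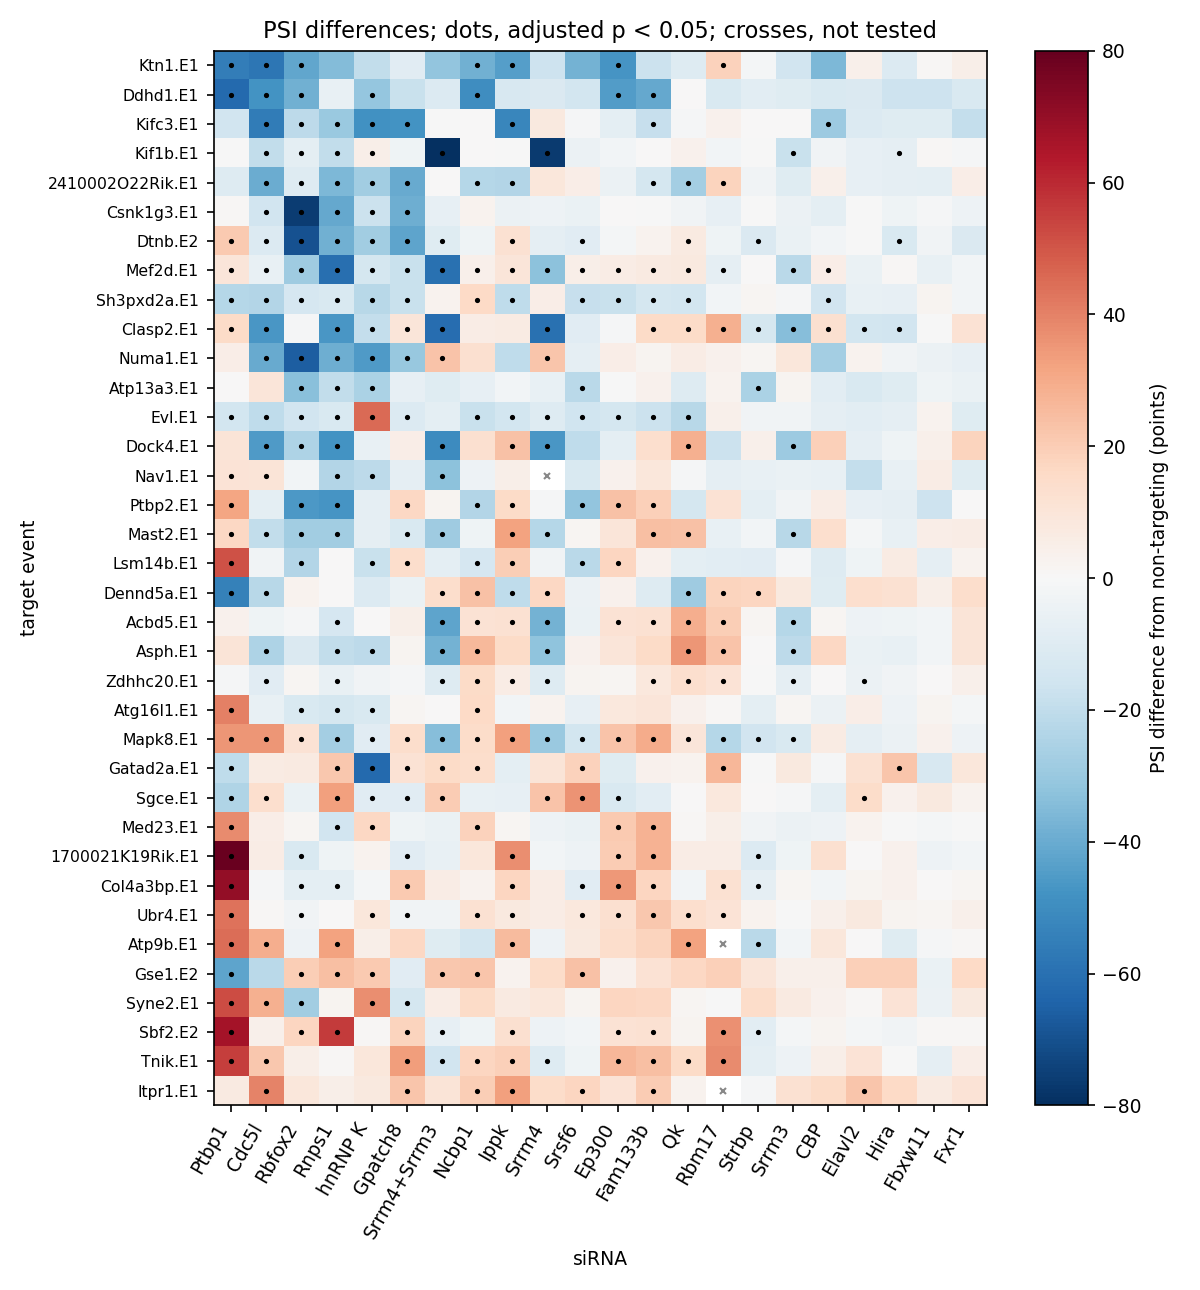
PSI differences from non-targeting libraries in points for 36 target events shown among those called with 10 points or more in at least 5 knockdowns; dots mark an adjusted p under 0.05 and crosses pairs that were not tested. Mef2d.E1 ranged from -60.1 points with Rnps1 to 9.9 points with Ptbp1 siRNA.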

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

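The test of loss of other amplicons was chosen after the larger share of Khdrbs1 was seen, and what it should give was written before the result of that test was seen. Khdrbs1 encodes Sam68, an RNA-binding protein that regulates splicing, and its amplicon was on the panel although its RNA was not a target of any siRNA. With siRNA against Cdc5l, a protein of the spliceosome, the Khdrbs1 amplicon took 25.2 ± 1.77 reads per 10000 (SD, n = 2) against 16.2 ± 0.62 in non-targeting libraries (log2 change 0.64, SE 0.20, limma adjusted p = 0.00492), higher in 2 of 2 libraries. With siRNA against the splicing factor Srsf6 it took 30.8 ± 10.3 (log2 change 0.89, SE 0.20, limma adjusted p = 8.4e-04), and without Srsf6 replicate 1 the call was lost (log2 change 0.54).

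The larger share may reflect loss of other amplicons from the total, since shares add up to a fixed sum and 55 of 77 amplicons were called with Cdc5l siRNA and 37 with Srsf6 siRNA. When libraries were scaled by the median ratio of amplicons instead, the log2 changes were 0.78 for Cdc5l and 0.72 for Srsf6 (SE 0.18). Khdrbs1 thus rose relative to the median amplicon. That scaling assumes that most amplicons did not change, so with this many calls it cannot exclude loss of many other amplicons. Of the called amplicons 24 were higher and 31 lower with Cdc5l siRNA, and 25 and 12 with Srsf6 siRNA, so Khdrbs1 was not alone in rising. Loss of many other amplicons, a change in the amount of Khdrbs1 RNA and a change in the efficiency of the multiplex PCR all remain open. The data analysed here cannot separate them.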

How the results depend on the processing

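The quasi-binomial test and the other settings listed as added in the methods were chosen after the result was seen, as were all alternatives for amplicon shares, and the other settings before. Where a value moved, the cause was not tested. A fit on only the groups compared keeps the log2 odds ratios and changes only the estimate of the spread, which rests on fewer libraries. Leaving out a library leaves a lone library in its group, which widens the SE. A call lost in these settings does not by itself tell an unstable effect from lower power.

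The number of events called with Srrm3 siRNA was 22 instead of 13 when the mean of the other groups with the same i5 barcodes was the reference. Double knockdown against Srrm4 gave 3 instead of 13 events when a difference of 10 points was also required. Ep300 against CBP gave 17 instead of 29 with at least 100 reads and 18 in a fit on only the groups compared. With 1 library left out, counts ranged from 21 to 27 for Srrm4, 9 to 12 for Srrm3, 27 to 35 for the double knockdown, 35 to 38 for Rnps1 and 0 to 1 for untreated. They ranged from 8 to 14 for the double knockdown against Srrm4, 23 to 27 against Srrm3, 16 to 22 for Ep300 against CBP and 404 to 527 over the 22 knockdowns. The shared lower events of Rnps1 and Srrm4 ranged from 12 to 15, and the interaction gave 0 calls by limma in each of 8 runs.

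Some log2 odds ratios of named events reversed. Eif4g3.E2 with Srrm4 siRNA, 0.06 in the test over all groups, was -0.11 against untreated, -0.03 against the mean of both controls and from -0.03 (without non-targeting replicate 2) to 0.14 (without non-targeting replicate 1) with 1 library left out. Against the groups with the same i5 barcodes Senp6.E1 with Srrm3 siRNA was 0.04, Eif4g3.E2 was 0.20 with Srrm3 and 0.06 with both siRNAs, and with Elavl2 siRNA Clasp2.E1 was 0.50 and Zdhhc20.E1 0.01. For Senp6.E1, Clasp2.E1 and Zdhhc20.E1 that reference includes Srrm4 and Rnps1 libraries, in which these exons fell. These reversals cannot tell an unstable effect from a lowered reference. Of 190 values for named events, 149 kept their label in a fit on only the groups compared and 41 were weaker. With the replicate block and the quasi-binomial test all 190 kept it. Of 760 values with 1 library left out, 638 kept their label and 121 were weaker.

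The DESeq2 alternative and the trended edgeR dispersion were not run. The 4 results on microexons versus longer exons, with their alternatives on the microexon limit, the scale, a PSI range of 5 to 95 and the set test, were not computed. The interaction had no quasi-binomial run.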

Other observations

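The comparison with Ptbp1 was picked after 231 pairs of profiles had been viewed, and the tests on shared controls, i5 barcodes, Ptbp2 and the Srrm4 amplicon were chosen after the result was seen; what the test without the largest events should give was written before its own result was seen. Some exons were called in many knockdowns, and since all calls share 2 non-targeting libraries, calls were also counted against untreated and against the mean of the other groups with the same i5 barcodes, a reference that itself moves with events that respond often. Clasp2.E1 was called in 15 of 22 knockdowns, 9 lower and 6 higher (10 and 4 against untreated, 6 and 13 against the same i5 barcodes), from -61.0 points in double-knockdown to 28.3 points in Rbm17 libraries. Sh3pxd2a.E1, in the gene of the podosome scaffold Tks5, was called in 13, 12 lower and 1 higher (12 and 1 against untreated, 7 and 9 against the same i5 barcodes). Senp6.E1 was lower in 10 and higher in 1 (11 and 0, 5 and 7), and Tnik.E1, in the gene of a kinase of the Wnt and JNK pathways, was lower in 2 and higher in 9 (1 and 9, 8 and 6). Dlg1.E2, in the synaptic scaffold gene, was called higher in 11 and lower in 0, but in 5 and 0 against untreated and in 4 and 3 against the same i5 barcodes by limma, so its tally depends on the non-targeting libraries. Dlg1.E2 was not the only such event. Cit.E1 was higher in 6 and lower in 3, but in 0 and 5 against untreated. Ubr4.E1 went from 9 and 2 to 2 and 3, and Kifap3.E1 from 1 and 2 to 13 and 0. No test of these tallies was run.

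Many amplicon shares differed between groups, 44 of 77 with Ptbp1, 11 with Qk, 55 with Cdc5l, 11 with Gpatch8 and 34 with both Srrm siRNAs. With median-of-ratios scaling these counts were 38, 7, 55, 12 and 33. The calls below are of 3 amplicons picked by hand, no gene group was tested, and each call was lost in at least 1 setting. The Srrm3 amplicon took 7.94 ± 1.82 reads per 10000 (SD, n = 2) with Ptbp1 siRNA against 13.5 ± 0.159 in non-targeting libraries (log2 change -0.78, limma adjusted p = 0.0398), a call lost with median-of-ratios scaling (-0.56) and without Ptbp1 replicate 2 (-0.55), non-targeting replicate 1 (-0.77) or non-targeting replicate 2 (-0.79). Against untreated libraries, where the Srrm3 amplicon took 20.4 ± 0.316, the log2 change was -1.37, so its size depended on the control. The Srrm4 amplicon took 18.7 ± 5.68 with Qk siRNA against 29.5 ± 6.61 (log2 change -0.68, limma adjusted p = 0.042), a call lost with median-of-ratios scaling (-0.62) and without Qk replicate 1 (-0.36), non-targeting replicate 1 (-0.90) or non-targeting replicate 2 (-0.45). The amplicon of Elavl3, a neuronal Hu protein gene, took 4.74 ± 1.06 with Cdc5l siRNA against 8.05 ± 1.76 (log2 change -0.74, limma adjusted p = 0.00306), a call lost without Cdc5l replicate 2 (-0.52) or non-targeting replicate 2 (-0.52). It took 5.14 ± 0.236 with Gpatch8 siRNA (log2 change -0.62, limma adjusted p = 0.0488), a call lost against untreated (-0.58) and without Gpatch8 replicate 1 (-0.57), Gpatch8 replicate 2 (-0.67) or non-targeting replicate 2 (-0.40). With both Srrm siRNAs it took 5.2 ± 0.574 (log2 change -0.61, limma adjusted p = 0.0207), a call lost without double-knockdown replicate 1 (-0.50) or non-targeting replicate 2 (-0.39). Shares after an endpoint PCR are not expression levels.

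Ep300, Fam133b and Ippk siRNA gave profiles that resembled that of Ptbp1, the repressor of neuronal exons. With untreated libraries as the control of 1 side, the r of log2 odds ratios with Ptbp1, averaged over the 2 choices of that side, was 0.73 for Ep300, 0.63 for Fam133b and 0.59 for Ippk, with a lowest single value of 0.51, so the shared non-targeting control may not account for it. Over all 231 pairs of knockdowns the median of this r was 0.21. The likeness was not particular to Ptbp1: r was 0.66 for Fam133b with Ep300, 0.65 for Ippk with Fam133b and 0.61 for Ippk with CBP. CBP itself had an r of 0.24 with Ptbp1. Fam133b and Ippk share the Ptbp1 row of i5 barcodes and Ep300 does not. All other knockdowns of that row, Fam133b and Ippk included, had a median r of -0.01 (-0.09 without these 2), which speaks against the row alone. Without the 10 events of largest change with Ptbp1 siRNA the lowest r of the 3 was 0.55. This speaks against a few events with very large changes in Ptbp1 libraries. Events with large changes in only the other knockdowns were not left out. Events that share an amplicon's reads, such as Mapk8.E1 and Mapk8.e2, counted separately in r. Lower Ptbp1 activity in the 3 knockdowns may be a cause and stays open: Ptbp2.E1 was called higher in 3 of 3, at 90.1% ± 0.9, 86.0% ± 5.1 and 82.0% ± 0.4 against 66.8% ± 1.1 in non-targeting libraries, but this event is part of the profiles and only restates their likeness. The level of Ptbp1 and off-target effects of the siRNAs were not tested.

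Rnps1 and Srrm4 siRNA lowered many of the same exons, among them Mef2d.E1, Clasp2.E1 and Kif1b.E1. The likeness was not particular to Srrm4. With the controls split, the mean r of log2 odds ratios of Rnps1 was 0.57 with both Srrm siRNAs and 0.53 with Srrm4. It was 0.54 with Srsf6, 0.54 with Elavl2 and 0.53 with Hira. A shared non-targeting control may raise such an overlap, but with the controls split the lower covariance of log2 odds ratios was 2.00 (SD 0.53), against 0.15 in simulated pairs of unchanged groups. The r of log2 odds ratios was 0.55 with the shared control, and 0.47 and 0.58 with the controls split, for which no r was simulated. Simulated unchanged groups with the shared control had a mean r of 0.49. That value follows from the shared control noise alone, with no effects in it, so the observed r cannot be judged by it. Rnps1 siRNA may act by lowering Srrm4 RNA, but the log2 change of the Srrm4 amplicon was 0.16 (SE 0.22). Whether Srrm4 protein changed, or both proteins act on the same exons, remains open.

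The scores that the authors deposited for 33 events came from the same libraries and are not an independent test. Of 726 pairs of event and knockdown with a score, 484 were tested here and 163 called, and in 163 of them the score had the sign of the PSI difference, Kif1b.E1 with Srrm4 siRNA among them.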
